A study of Mus musculus with 4 samples.

How the data were processed

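Total RNA from mouse synovium was measured on 4 Affymetrix MoGene 2.0 ST arrays, each hybridised with RNA from 1 pool of mice. The pools were 2 of nonarthritic synovium, each from 3 mice, and 2 of arthritic synovium on day 10, each from 10 mice. Per the labels' protocols, the tissue came from around the tibiotalar (ankle) joint of male C57BL/6J mice aged 12 weeks, and 500 ng of total RNA was labelled for each array. Arthritis was induced with 3 intraperitoneal injections, on day 0, day 2 and day 7, each of 150 microlitres of serum that transfers the disease, and nonarthritic mice received saline, per the same protocols. The labels give K/BxN as the serum source strain for all 4 pools and day 0 as the time point of the nonarthritic pools. For the nonarthritic pools the serum label conflicts with the saline of the protocols, and the day their tissue was taken is not clear. The groups also differ in labelled day and in pool size.

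The values are the deposited log2 signals of the authors, 1 per probe set and array, rounded to 2 decimals. Per the submitters' processing notes, Affymetrix Expression Console, Affymetrix Power Tools and RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a probe set) were used. Their versions and settings are not given in the sources used here. The log2 scale was inferred from the values, which ran from 2.89 to 14.27. The array medians over 41345 probe sets were 7.05 and 7.15 for nonarthritic pools 1 and 2, and 6.96 and 7.05 for arthritic pools 1 and 2. No detection calls or background signals were used, so a low value cannot be told from background. Where the signal of a group lies near the medians of olfactory receptor genes on these arrays, 4.60 to 5.15, a fold change is a lower bound. Of the genes named, this holds for the arthritic signals of Retnla, Rnase2a, Scg3, Cdh19, Ms4a1, Epcam and Car1 and for the nonarthritic signals of Stfa2l1, Il6 and H2ac15. The number of arrays limits the precision.

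Probe sets were named through the platform's probe-to-gene table. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Symbols were checked by gene number against a RefSeq gene table of assembly GRCm38.p6: 23328 matched and 0 were renamed. Only probe sets with 1 symbol were named, and each gene was represented by its probe set with the highest mean over the 4 arrays, which left 22180 genes. Of these, 1082 had more than 1 probe set and none had probe sets called in opposite directions. Of the 208 of these genes that were called, 91 lost the call when their probe sets were averaged. Probe sets of a gene could still differ in size: those of Ckm gave log2 fold changes of -2.84 and -0.32, and those of Rplp0 gave 1.02 and 0.02. Genes of families with near-identical copies, such as Stfa2l1, Rnase2a, Retnla, Retnlg, Hspa1a and Hspa1b, histone genes and ribosomal protein genes, can share probes, and their values are uncertain for that reason.

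Arthritic and nonarthritic synovium were compared gene by gene with limma 3.58.1 (lmFit and eBayes with a constant variance prior, 2-sided) in R 4.3.3, with no block. A positive log2 fold change is higher in arthritic synovium. Adjusted p-values are Benjamini-Hochberg values over the 22180 genes, and a gene was said to rise or fall when its adjusted p was under 0.05. There were 2 residual degrees of freedom and the prior added 5.98. The 2 pools of a group stood at least 2-fold apart for some named genes, whose fold changes are less certain. In nonarthritic synovium these were Cxcl5, Mmp9, Il1b, Mmp13, Stfa2l1, Rnase2a, Il6, Slpi, Tnfsf11, Cthrc1, Egln3, Fos, Saa3, S100a9, Mmp3, Acod1, Clec4d and Stfa1. In arthritic synovium they were H1f5, Cyp2e1, Scg3, Lyve1, Ptgs2, Omd, Frzb, Bmp4, Matn3, Egln3, Cox8b, Fos and Adipoq. Errors of single values are SD over 2 pools, and those of fold changes are the SE from limma. The series' design text calls the pools biological replicates, and p-values of the gene test measure the spread between pools, not between mice.

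Before the data were examined, 42 gene lists were fixed, covering cell types of the joint and of neighbouring tissue, inflammation, matrix turnover, bone, signalling and metabolism. Of their 908 genes, 834 were measured. The others, among them Spp1, Runx2 and the haemoglobin genes, were not analysed here. Of the fixed genes, 41 stood in several lists, such as Mmp9 in the neutrophil, metalloproteinase and osteoclast lists. Shifts of such lists are not independent of each other. Each list was set against all other genes with camera from limma at a preset correlation of 0.01, adjusted over the 42 lists. An estimated correlation and fry were alternatives. At the preset correlation, camera p-values rest mainly on the spread across genes, not between pools. Estimated correlations ran from -0.07 for protease inhibitors to 0.70 for blood vessel genes, with 0.50 for cell cycle and 0.51 for skeletal muscle genes. Where genes of a list correlate more strongly than the preset, its camera p-values are too small. The rule for named genes was fixed at the same time as the lists. It took the 10 largest rises and 10 largest falls among genes whose groups did not overlap (without predicted genes, clones and small RNAs), up to 3 rising and 3 falling members of each list, members that opposed most of their list, and a set of index genes whether or not they passed. Other genes are named only as members of a list.

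The alternatives were a filter on dim genes, the mean of a gene's probe sets, all probe sets tested, quantile normalization again, centring on array medians, trended and robust priors, a 2-fold limit, an adjusted p under 0.1, a block on pool number, and each pool left out in turn. With a pool left out, the lone pool was assumed to vary like the other group. Counts of list members without each pool were added after seeing the data.

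The gene test was tested on simulated data for arthritic against nonarthritic synovium with 22180 genes. It recovered 44% of 50 genes changed by log2 1, 98% of 50 changed by 2, and 100% of 50 each changed by 3 and by 4. There were 11 false among 182 calls. The simulated errors were normal and independent between genes, with SDs drawn from the variance prior fitted to these arrays. Control of false calls was therefore built in, and differences that many genes of an array share were left out. The 42 lists were simulated over 22180 independent genes. Camera with the preset correlation recovered 3 of 3 shifted lists with 0 false calls, and with an estimated correlation it recovered 0 of 3. Few false calls at the preset correlation were built in there too, since the genes of a list did not move together. Figures were drawn with matplotlib 3.10.9.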

Results

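Gene expression was measured in synovium, the tissue that lines the joint, from mice with serum transfer arthritis and from nonarthritic mice. In this model serum from arthritic mice carries autoantibodies that set off joint inflammation in the recipient. The 4 arrays held 2 nonarthritic pools of 3 mice each and 2 arthritic pools of 10 mice each, taken on day 10, which the labels name as the peak of inflammation. The comparison asks which genes differ between inflamed and nonarthritic synovium.

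Arthritic synovium differed from nonarthritic synovium in 3402 of 22180 genes: 1933 rose and 1469 fell (limma adjusted p under 0.05). At least 2-fold, 766 genes rose and 689 fell, and at least 8-fold, 27 rose and 48 fell. In all 3402 genes both arthritic pools lay on the same side of both nonarthritic pools, as 12503 of all 22180 genes did and as 33.3% would by chance. The first principal component held 79.1% of the variance and separated the groups, with nonarthritic pools 1 and 2 at -33.6 and -51.8 and arthritic pools 1 and 2 at 39.1 and 46.3. The SD of gene differences was 0.32 between the nonarthritic pools and 0.30 between the arthritic pools, against 0.53 to 0.68 between groups. Of the calls, 56.8% were rises, and 67.1% were rises when arrays were centred on their medians, which moved the median fold change of all genes from 0.005 to 0.1. The counts depend on each array: they were 637 higher and 584 lower without nonarthritic pool 1, and 144 and 209 without nonarthritic pool 2. Without arthritic pool 1 they were 232 and 418, and without arthritic pool 2 they were 47 and 105.

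Of the 10 largest rises, Capn6, a calpain-family gene, rose 17.0-fold, from 7.80 ± 0.65 to 11.89 ± 0.25 (mean log2 signal ± SD, n = 2 pools; adjusted p = 0.000187). Cxcl5, a chemokine that draws neutrophils, rose 14.7-fold (log2 fold change 3.88 ± 0.37 SE, adjusted p = 0.000562). The gelatinase Mmp9 rose by 3.84 ± 0.32 on the log2 scale, and the collagenase Mmp13 by 3.78 ± 0.74. The linker histone gene H1f5, the stefin Stfa2l1, the interleukin-36 gene Il1f9, the fibrillin Fbn2 and the calgranulin S100a8 had log2 fold changes of 3.84, 3.75, 3.70, 3.68 and 3.67. Il1b, which encodes interleukin-1 beta, rose from 8.23 ± 1.61 to 12.07 ± 0.38 (adjusted p = 0.00493). The nonarthritic pools stood more than 2-fold apart in 5 of these genes: in pools 1 and 2, Mmp13 read 10.59 and 7.72, Il1b 9.37 and 7.10, Cxcl5 8.40 and 7.06, Mmp9 9.01 and 7.88, and Stfa2l1 5.61 and 4.54. The log2 fold change of Cxcl5 was 4.54 without nonarthritic pool 1 and 3.21 without nonarthritic pool 2. Stfa2l1 belongs to a family with near-identical copies, and its nonarthritic signal of 5.08 was not shown to be above background, so its fold change is a lower bound.

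The largest falls reached further than the largest rises. Retnla, a secreted protein of macrophages in type 2 immunity, fell at least 128-fold, from 12.38 ± 0.53 to 5.37 ± 0.68 (adjusted p = 7.79e-05). The eosinophil-type ribonuclease gene Rnase2a was at least 74.8-fold and the chemokine gene Ccl17 40.5-fold lower. The log2 fold change was -4.91 ± 0.23 for Clec3a, a cartilage lectin, -4.80 ± 0.17 for the methyltransferase Inmt, -4.44 ± 0.28 for the complement component C7 and -3.93 ± 0.17 for Col10a1, the collagen of hypertrophic cartilage. Cyp2e1, the muscle gene Trdn and the granin Scg3 had log2 fold changes of -4.39, -4.37 and -4.22. The arthritic signals of Retnla (5.37), Rnase2a (5.12) and Scg3 (5.58) were not shown to be above background, since olfactory receptor genes had medians of 4.60 and 4.68 on these arrays. Their fold changes are therefore lower bounds. Retnla and Rnase2a have close copies, so their probes may read more than 1 gene.

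**Figure D1:**
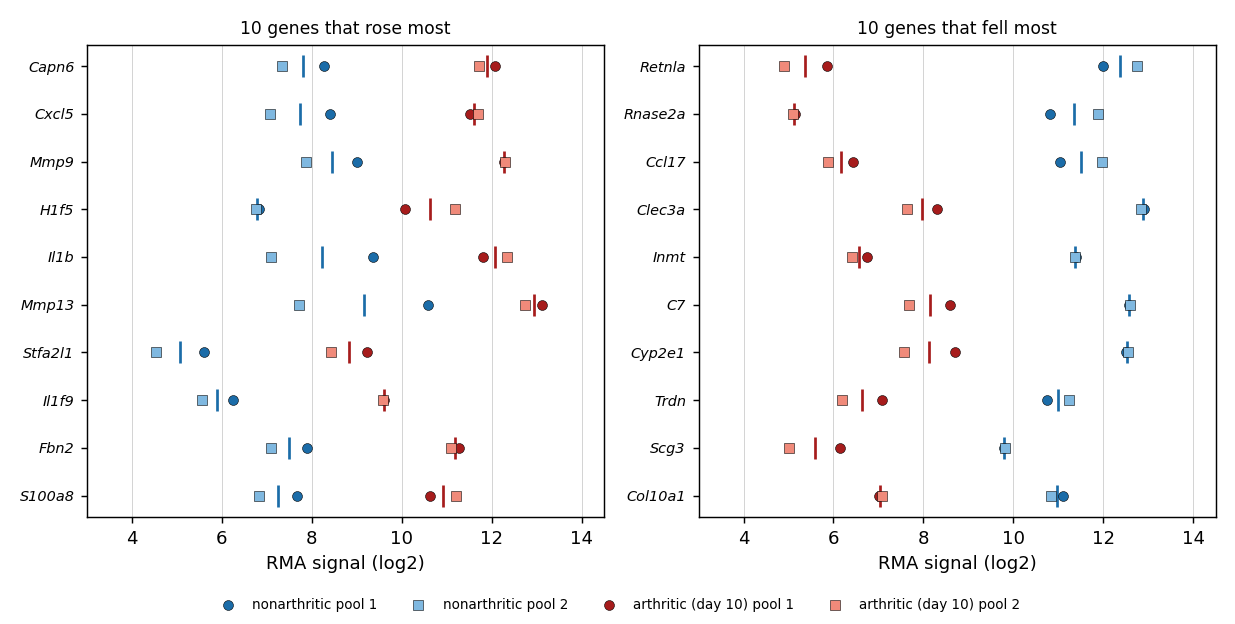
Log2 RMA signal (x axis) of the 10 genes that rose most and the 10 that fell most, with 1 point per pool and a bar at each group mean. Arthritic and nonarthritic pools do not overlap in any of the 20 genes, and the nonarthritic pools lie far apart for Mmp13 (10.59 and 7.72) and Il1b (9.37 and 7.10).

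Neutrophil genes rose together: 15 of 27 measured members rose and 0 fell (17 when adjusted over the list alone), with a median log2 fold change of 1.18. Among those that rose were the chemokine receptor Cxcr2 (3.63 ± 0.17), the collagenase Mmp8 (3.29), Csf3r (3.01) and S100a9 (2.94 ± 0.35), and Clec4e, Clec4d, Trem1 and Fpr2, which monocytes also make. The 12 that did not pass include the granule genes Mpo (0.14), Elane (-0.10), Ngp (0.57) and Camp (0.37) and the stefins Stfa1 (0.45), Stfa2 (-0.04) and Stfa3 (0.14). The list stood above other genes (camera adjusted p = 3.12e-12, and adjusted p = 0.55 with an estimated correlation). In simulation the estimated correlation recovered 0 of 3 shifted lists, so its values, here and below, cannot decide for or against a list. With nonarthritic pool 1, nonarthritic pool 2, arthritic pool 1 and arthritic pool 2 left out in turn, 13, 9, 12 and 4 neutrophil genes rose; later counts of this kind keep that order.

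Of 17 Fc receptor and partner genes, 8 rose and 0 fell (12 when adjusted over the list alone; median 0.53), led by the IgG receptor Fcgr4 (2.69 ± 0.17), the kinase Fgr (2.03) and Vav1 (1.74). The adjusted p from camera was 6.01e-08 for this list, and the adjusted p was 0.55 with an estimated correlation. Of 24 Toll-like receptor and inflammasome genes, 10 rose and 1, Tlr7 (-0.61), fell, also when adjusted over the list alone. Tlr1 (2.24), Nlrp3 (1.72) and Tlr2 (1.39) led them (camera adjusted p = 0.00532; adjusted p = 0.55 with an estimated correlation). That call also ended with the dim-gene filter (adjusted p = 0.0585) and with quantile normalization again (0.055). Interferon-stimulated genes had 11 rising and 0 falling members of 23, the same numbers when adjusted over the list alone, with Oasl2 at 1.57, Oas2 at 1.56 and Oas3 at 1.55. Their median was 0.64 (camera adjusted p = 0.000104; adjusted p = 0.55 with an estimated correlation). Leaving out the pools in turn gave 4, 2, 3 and 1 rising Fc receptor genes, 3, 1, 1 and 0 Toll-like receptor genes and 6, 0, 2 and 0 interferon-stimulated genes.

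Proinflammatory cytokine genes split. Of 22, 7 rose and 2 fell (9 and 3 when adjusted over the list alone), and the list did not stand apart (median 0.27, camera adjusted p = 0.111, and 0.0439 without arthritic pool 1). The prostaglandin synthase Ptgs2 rose by 3.02 ± 0.37, Il6 by 2.69 ± 0.53 and Tnf by 0.88 ± 0.16 on the log2 scale, while Tslp (-1.21) and the B cell factor Tnfsf13b (-0.92) fell. Il17a was at 0.08 ± 0.16 (adjusted p = 0.797). Another list held 17 cytokine antagonists and anti-inflammatory genes, called antagonists for short in this paragraph. Of these 17, 6 rose, led by the interleukin-1 receptor antagonist Il1rn (2.12), the decoy receptor Il1r2 (1.78) and Tnfrsf1b (1.18). Another 3 of the 17 fell: Alox15 (-1.40), Alox12 (-0.71) and Tsc22d3 (-0.67). The numbers were the same when adjusted over the list alone, and camera gave an adjusted p of 0.179. Leaving out the pools in turn left 3, 1, 3 and 0 rising cytokine genes and 2, 0, 2 and 0 rising antagonists. Il6 read 6.61 and 4.83 in nonarthritic pools 1 and 2.

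Chemokines moved both ways. Of 28, 12 rose and 5 fell (14 and 6 when adjusted over the list alone; median 0.55). After Cxcl5, the largest rises were Ccl3 (2.49 ± 0.28), which draws monocytes, and the neutrophil chemokine Cxcl2 (2.23 ± 0.25). The 5 that fell were Ccl17, Ccl24 (-2.44), Ccl11 (-1.86), Ccl22 (-1.01) and Pf4 (-0.55). Of these Ccl17 and Ccl22 act through a receptor of T cells, and Ccl11 and Ccl24 draw eosinophils. Camera placed the list above other genes (adjusted p = 0.0102; adjusted p = 0.55 with an estimated correlation). This call was lost with the dim-gene filter (adjusted p = 0.158) and with quantile normalization again (0.0897). Leaving out the pools in turn gave 7, 5, 7 and 1 rising and 4, 2, 3 and 2 falling chemokines. Acute phase genes had 6 rising and 2 falling members of 16 (7 and 3 when adjusted over the list alone; camera adjusted p = 0.0984, and 0.0199 without nonarthritic pool 2). Saa3 rose by 3.54 ± 0.46 on the log2 scale (4.40 without nonarthritic pool 1 and 2.68 without nonarthritic pool 2), and Orm1 (-2.07) and Cp (-1.45) fell. Without the pools in turn, 6, 3, 2 and 1 acute phase genes rose.

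Macrophage and monocyte genes did not shift as a list: 9 of 26 rose and 4 fell (10 and 4 when adjusted over the list alone; median 0.22, camera adjusted p = 0.279). Mpeg1 (1.91), the high-affinity IgG receptor Fcgr1 (1.59) and the nitric oxide synthase Nos2 (1.34) rose. The 4 that fell are markers of tissue-resident macrophages: Lyve1 (-2.59 ± 0.30), Vsig4 (-2.06 ± 0.19), Timd4 (-1.79 ± 0.15) and Cd163 (-1.49 ± 0.21). With the pools left out in turn, 3, 1, 1 and 0 rose and 2, 1, 3 and 1 fell. MHC class II presentation genes had 1 rising member of 10, H2-Oa (0.94), also when adjusted over the list alone. Their median was -0.04, their mean 0.11 and camera's direction up (adjusted p = 0.636).

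Of 21 T and NK cell genes 4 rose, also when adjusted over the list alone, among them the protease Gzmb (2.17), Cd4 (1.74) and Thy1 (0.68), which fibroblasts also carry (camera adjusted p = 0.0644, and 0.0385 with quantile normalization again and 0.0065 without nonarthritic pool 2). Of 15 B cell and plasma cell genes 3 rose and 4 fell (3 and 5 when adjusted over the list alone). Sdc1 (1.16), Prdm1 (1.02) and Cd22 (0.91) rose, and Ms4a1 (-1.74), Ighm (-1.18) and Cd79a (-1.18) fell (camera adjusted p = 0.0672, and 0.0344 without arthritic pool 2). Other probe sets of Ighm gave -0.39 to -0.54 and, for 1 of them, -1.48. Mast cell genes shifted down, with 4 of 12 falling and 1 rising (6 and 1 when adjusted over the list alone; median -0.39). Ms4a2 (-1.64), Mrgprb2 (-1.37) and Mrgprb1 (-1.12) fell, and the histamine-forming enzyme Hdc, which neutrophils can also make, rose by 2.68 ± 0.19 on the log2 scale. In camera the adjusted p was 0.0317 for mast cell genes, and the adjusted p was 0.55 with an estimated correlation. It was 0.207 with the dim-gene filter and 0.131 without nonarthritic pool 1. Of 8 red cell precursor genes Sptb (-0.92) and Car1 (-0.66) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.0972, and 0.0384 without arthritic pool 2). With each pool removed, 1, 0, 2 and 0 mast cell genes fell.

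Adhesion molecules for leukocytes rose in 8 of 19 cases and 1, Jam2 (-0.88), fell (10 and 2 when adjusted over the list alone; median 0.51). The integrin Itgal (1.54), the selectin ligand Selplg (1.51) and Selp (1.45) led the list (camera adjusted p = 0.0061; adjusted p = 0.55 with an estimated correlation). The dim-gene filter (adjusted p = 0.0556) and quantile normalization again (0.0624) ended the call. Complement genes had 8 rising and 4 falling members of 24 (10 and 4 when adjusted over the list alone; camera adjusted p = 0.203). Masp1 (1.37), Cfi (1.35) and Cfp (1.08) rose, while C7, the membrane regulators Cd55 (-1.44) and Cd46 (-0.86), and C4b (-0.80) fell. When pools were dropped in turn, 3, 0, 2 and 0 adhesion genes and 3, 0, 0 and 0 complement genes rose.

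Enzymes that break down matrix rose more often than they fell. Of 22 matrix metalloproteinases and aggrecanases, 11 rose and 2 fell (13 and 3 when adjusted over the list alone; median 0.81). Mmp9 and Mmp8 are also in the neutrophil list. Besides Mmp9, Mmp13 and Mmp8, the stromelysin Mmp3 rose from 9.49 ± 0.72 to 12.10 ± 0.37 and the aggrecanase Adamts4 by 2.38 on the log2 scale, while Adamts5 (-0.87) and Mmp12 (-0.81) fell. The list stood above other genes (camera adjusted p = 1.17e-05; adjusted p = 0.55 with an estimated correlation). Of 11 protease inhibitors, Slpi (3.31), Timp1 (2.01 ± 0.19) and A2m (1.08) rose and Timp4 (-2.52) and Timp3 (-1.19) fell, 3 and 2 genes (3 and 4 when adjusted over the list alone). Their median was -0.27, their mean 0.11 and camera's direction down (adjusted p = 0.561). With pools left out in turn, 9, 4, 3 and 2 proteases and 2, 2, 1 and 0 inhibitors rose.

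Matrix genes rose broadly. Of 29 fibrillar collagen and matrix genes, 20 rose and 0 fell (22 rose and 1 fell when adjusted over the list alone; median 0.80). Cthrc1 (2.29 ± 0.34), Col12a1 (2.18 ± 0.23) and tenascin C, Tnc (2.13 ± 0.22), rose most, and Col1a1 rose by 0.59 on the log2 scale. Camera gave an adjusted p of 1.77e-09 (adjusted p = 0.55 with an estimated correlation). All 29 members read higher on nonarthritic pool 1 than on pool 2, with a median difference of 0.23. Tendon genes had 4 rising members of 9 (4 rising and 1 falling when adjusted over the list alone), among them Scx (1.52), Kera (1.35) and Col14a1 (1.12), with a median of 0.61 (camera adjusted p = 0.0373; adjusted p = 0.569 with an estimated correlation). Tendon genes were not called with quantile normalization again (adjusted p = 0.149), without nonarthritic pool 2 (0.12) or without arthritic pool 1 (0.139). Without the pools in turn, 11, 3, 1 and 0 matrix genes and 1, 0, 0 and 0 tendon genes rose.

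Cartilage and synovial fibroblast genes split. Of 23 chondrocyte genes 8 rose and 5 fell (11 and 6 when adjusted over the list alone). Col11a1 (2.40), Matn3 (2.31), aggrecan, Acan (2.02), and Col2a1 (0.86 ± 0.20) rose. Col10a1, Chad (-3.62 ± 0.21), Cytl1 (-3.51 ± 0.18), Sox6 (-1.29) and Sox5 (-0.74) fell. Their median was 0.60, their mean 0.08, and fry gave the direction down, with camera adjusted p = 0.23, and 0.043 without arthritic pool 2. Of 20 synovial fibroblast genes 4 rose and 5 fell (7 and 7 when adjusted over the list alone). Cdh11 (1.70), Vcam1 (1.45), Pdpn (1.19) and Thy1 (0.68) rose, and Clic5 (-2.48), Htra4 (-1.89) and Cd55 fell. Lubricin, Prg4, was at -0.27 ± 0.16 (adjusted p = 0.343). The adjusted p from camera was 0.875 for synovial fibroblast genes, with a median of -0.02, direction down in camera and up in fry. With each pool removed, 2, 2, 1 and 2 chondrocyte genes rose and 3, 3, 4 and 3 fell, and 3, 1, 1 and 0 fibroblast genes rose and 0, 0, 3 and 1 fell.

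Genes of bone resorption rose. Of 20 osteoclast genes 11 rose and 0 fell (13 when adjusted over the list alone). Tnfsf11, the osteoclast-inducing ligand RANKL, rose from 6.79 ± 0.83 to 9.44 ± 0.13 (adjusted p = 0.00184). Oscar rose by 2.23 ± 0.21, Acp5 by 1.42 ± 0.17 and the collagen-degrading cathepsin Ctsk by 0.67 ± 0.18 on the log2 scale. In camera the adjusted p was 4.6e-07 (adjusted p = 0.55 with an estimated correlation). Tnfsf11 read 7.38 and 6.21 in nonarthritic pools 1 and 2. Osteoblast and mineralisation genes shifted down, with 8 of 17 falling and 2 rising (12 and 2 when adjusted over the list alone; median -0.87). Omd (-2.28), Tnfrsf11b, the decoy receptor for RANKL (-1.89 ± 0.21), and Phex (-1.86) fell, and Pth1r (0.69) and Col1a1 (0.59) rose. Camera gave an adjusted p of 8.76e-05, and the adjusted p was 0.55 with an estimated correlation. Of the 17 genes, 14 read higher on arthritic pool 1 than on arthritic pool 2, with a median difference of 0.52. Over the 4 omissions, 8, 3, 3 and 1 osteoclast genes rose and 1, 1, 6 and 0 osteoblast genes fell.

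Wnt antagonists fell more often than they rose. Of 20 antagonists and feedback targets 9 fell and 3 rose, also when adjusted over the list alone (median -0.30). Wif1 (-2.02 ± 0.17), Frzb (-1.91 ± 0.36), Sfrp5 (-1.58 ± 0.16), Sfrp4 (-1.22 ± 0.24) and Dkk1 (-0.68 ± 0.17) fell. Sfrp2 (2.19 ± 0.22), Sfrp1 (1.64 ± 0.21) and Dkk3 (0.93 ± 0.26) rose. Frzb read 8.28 and 6.99 in arthritic pools 1 and 2. Axin2, a feedback target of Wnt signalling, was at -0.41 ± 0.16 (adjusted p = 0.132), and at 0.03 on its second probe set. The adjusted p from camera was 0.0305 (adjusted p = 0.55 with an estimated correlation), and the call was lost without nonarthritic pool 1 (adjusted p = 0.102) and without arthritic pool 2 (0.0686). Of 36 Wnt ligands and receptors 6 rose and 3 fell (7 and 3 when adjusted over the list alone; camera adjusted p = 0.146). Fzd1 (1.12), Fzd2 (1.03) and Lgr5 (0.99) rose, and Fzd4 (-1.09), Wnt11 (-0.83) and Rspo3 (-0.70) fell. A second probe set of Lgr5 gave 0.32, and one of Sfrp2 gave 1.20. With the pools left out in turn, 3, 3, 5 and 0 antagonists fell, 1 rose in each case, and 0 ligands or receptors passed.

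BMP and TGF-beta genes showed no common shift: 5 of 37 rose and 7 fell (6 and 10 when adjusted over the list alone; camera adjusted p = 0.238). The latent TGF-beta binding proteins Ltbp2 (1.40) and Ltbp1 (0.71), Chrdl2 (1.25), Bmp1 (0.89) and Fstl1 (0.60) rose. Bmp4 (-2.33 ± 0.37), Bmp6 (-1.82 ± 0.20) and Bmp3 (-1.27 ± 0.16), ligands of the family, fell. Bmp4 read 9.08 and 7.72 in arthritic pools 1 and 2. With pools left out in turn, 2, 0, 4 and 0 of these genes fell.

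**Figure D2:**
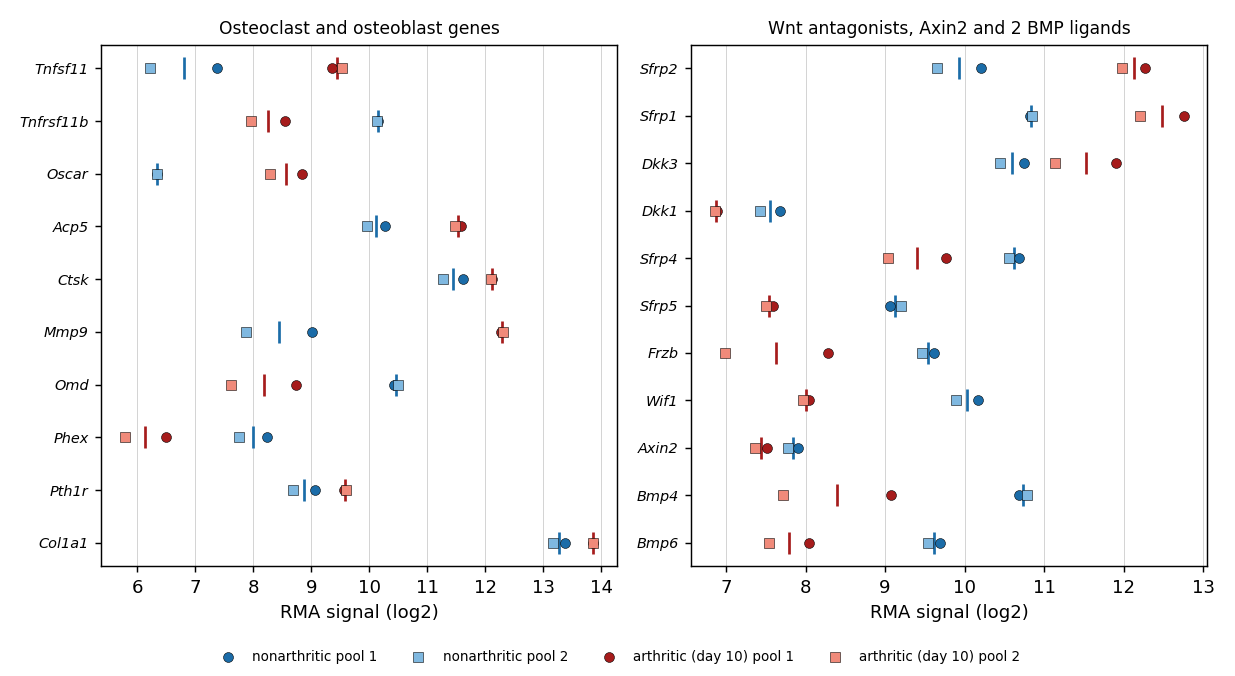
Log2 RMA signal (x axis) of 10 genes of bone resorption and bone formation (left) and of Wnt antagonists, Axin2 and 2 BMP ligands (right), with 1 point per pool and a bar at each group mean. Tnfsf11 was higher and Tnfrsf11b lower in both arthritic pools, and Sfrp2 rose by 2.19 where Wif1 fell by 2.02 on the log2 scale.

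Cell cycle genes rose almost without exception: 31 of 32 rose, also when adjusted over the list alone, and the median was 1.51. Cdk1 (2.51 ± 0.30), Plk1 (2.37 ± 0.20) and Kif20a (2.31 ± 0.22), which drive mitosis, rose most. The proliferation marker Mki67 rose by 1.65 ± 0.20 on the log2 scale, and Pcna, at 0.04, was the member that did not pass. In camera the adjusted p was 2.9e-23 (adjusted p = 0.55 with an estimated correlation). When pools were dropped in turn, 23, 8, 14 and 0 rose, and 26 of the 32 read higher on nonarthritic pool 1 than on pool 2. Of 28 ribosomal protein genes 9 rose and 0 fell (15 when adjusted over the list alone; median 0.47), among them Rplp0 (1.02), Rpl7 (0.89) and Rps19 (0.86). Camera gave an adjusted p of 1.81e-06 (adjusted p = 0.55 with an estimated correlation), and 0 of them passed with any 1 pool left out. The other probe sets of Rplp0 and Rpl7 gave 0.02 and 0.23, and the others of Rps19 gave 0.86 and 0.22.

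Stress genes moved in both directions. Of 19 unfolded protein response genes 3 rose and 1 fell, also when adjusted over the list alone: Pdia6 (1.18), Edem1 (0.73) and Hspa5 (0.60) against Dnajb9 (-0.64). Their median was 0.25 (camera adjusted p = 0.0467; adjusted p = 0.559 with an estimated correlation). The call ended with the dim-gene filter (adjusted p = 0.2), quantile normalization again (0.212) and median centring (0.0552), and without nonarthritic pool 2 (0.126) or arthritic pool 2 (0.0749), and 1, 0, 0 and 0 rose without the pools in turn. Of 21 oxidative stress genes 5 rose and 2 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.16). The cystine transporter Slc7a11 rose by 2.99 and haem oxygenase, Hmox1, by 1.52 on the log2 scale, with Gsr at 1.43, while Gclc (-0.70) and Sod1 (-0.62) fell. Second probe sets of Slc7a11 and Edem1 gave 1.13 and 0.15. Of 19 immediate early and heat shock genes 4 rose and 2 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.886): Fos (1.52), Junb (1.04) and Ier2 (0.97) against Hspa1b (-2.67) and Hspa1a (-1.51). Without the pools in turn, 3, 1, 4 and 0 oxidative stress genes and 1, 0, 0 and 0 immediate early genes rose.

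Markers of muscle, fat and nerve, which lie beside the joint, fell. Lists of other neighbouring tissue did not fall in this way, with medians of 0.61 for tendon and -0.03 for keratinocyte genes. Of 27 skeletal muscle genes 22 fell and 0 rose, also when adjusted over the list alone (median -2.53). Nebulin, Neb (-3.81 ± 0.25), Casq1 (-3.73 ± 0.20) and titin, Ttn (-3.66 ± 0.18), fell most, and Ckm fell by 2.83 on the log2 scale. Slow-fibre genes did not pass, with Myl2 at 0.17, Tnni1 at -0.01, Tnnt1 at -0.07, Tnnc1 at -0.20 and Myh7 at -0.23. This does not show that slow fibres were spared. Myl2 lay below the median level of all genes, where background can hide a fall. Of 22 adipocyte genes 18 fell and 0 rose, also when adjusted over the list alone (median -1.96), with Cidec at -3.40 ± 0.17, Retn at -3.31 ± 0.20, Plin1 at -2.94 and Adipoq at -2.55 ± 0.31. Of 12 Schwann cell and nerve genes 9 fell (10 when adjusted over the list alone; median -0.89), led by Cdh19 (at most -2.39, with an arthritic signal of 5.59 not shown to be above background), S100b (-1.90) and Mal (-1.81). Camera gave adjusted p = 1.71e-22, 2.64e-18 and 1.69e-07 for the muscle, adipocyte and nerve lists, and adjusted p = 0.55 with an estimated correlation for each. Over the 4 omissions, 21, 16, 19 and 9 muscle genes, 11, 9, 14 and 5 adipocyte genes and 5, 2, 2 and 1 nerve genes fell. The pools of a group differed in muscle genes: 0 of 27 read higher on nonarthritic pool 1 than on pool 2, and 20 read higher on arthritic pool 1 than on pool 2.

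Vessel and skin lists moved little beside these. Of 13 smooth muscle and pericyte genes 4 fell and 0 rose (6 fell and 1 rose when adjusted over the list alone; median -0.41), with Des, also in the muscle list, at -1.42 and Synpo2 and Myh11 at -1.41. The adjusted p from camera was 0.0122 (adjusted p = 0.569 with an estimated correlation), and 0.0972 without arthritic pool 2. Of 22 blood vessel endothelial genes 5 rose and 0 fell (7 and 2 when adjusted over the list alone), led by Aplnr (1.57), Selp and Sele (1.33). Their camera adjusted p was 0.0467 (adjusted p = 0.677 with an estimated correlation). The call was also lost with the dim-gene filter (adjusted p = 0.2), quantile normalization again (0.256), median centring (0.0624), without nonarthritic pool 2 (0.154) and without arthritic pool 1 (0.507). Of 7 lymphatic endothelial genes Pdpn rose and Reln (-1.07) and Lyve1 fell (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.23, and 0.024 without arthritic pool 1). Of 19 keratinocyte genes Krtdap (-2.81) and Epcam (-1.06) fell, 2 also when adjusted over the list alone (camera adjusted p = 0.187). With each pool removed, 2, 0, 0 and 0 blood vessel genes rose and 1, 0, 2 and 0 smooth muscle genes fell.

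Genes of energy metabolism did not shift as lists, and several that fell are forms made in muscle. Of 36 oxidative phosphorylation genes Ndufa2 (0.98) rose and 3 muscle forms of cytochrome oxidase subunits fell, Cox8b (-3.36), Cox7a1 (-2.54) and Cox6a2 (-2.52), also when adjusted over the list alone (camera adjusted p = 0.389). Of 24 glycolysis and hypoxia genes 5 rose and 4 fell (9 and 4 when adjusted over the list alone; camera adjusted p = 0.285). Pfkl (1.29), Slc16a3 (1.10) and Pgam1 (0.94) rose, and Egln3 (-2.06), the muscle phosphofructokinase Pfkm (-1.83), Bnip3 (-0.88) and Ndrg1 (-0.79) fell. Of 20 fatty acid oxidation genes 3 rose and 4 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.23). Acads (0.65), Slc25a20 (0.65) and Cpt1a (0.64) rose, and Ppargc1a (-1.60), Cd36 (-1.55) and Pdk4 (-1.11) fell. A second probe set of Ndrg1 gave -0.04. These falls stand beside a median of -2.53 for skeletal muscle genes. Of 2 genes often used as references, Gapdh was at 0.06 ± 0.16 (adjusted p = 0.871) and Actb rose by 0.84 ± 0.15 on the log2 scale (adjusted p = 0.00916).

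**Figure D3:**
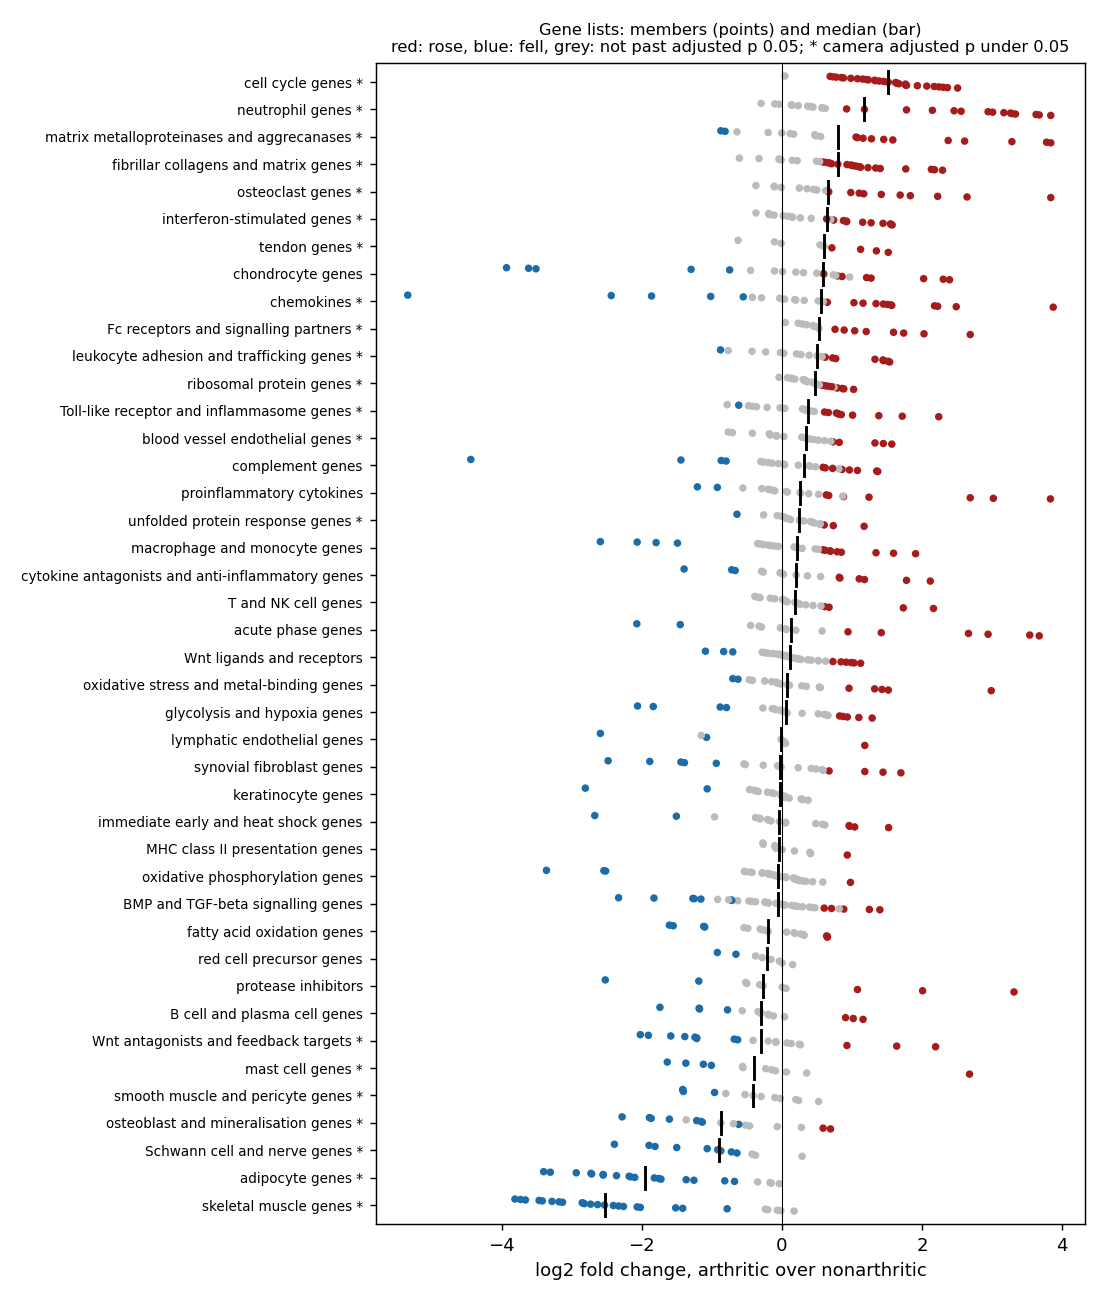
Log2 fold changes (x axis, arthritic over nonarthritic) of the measured members of the 42 lists, with 1 point per gene and a bar at each list's median. Red points rose, blue points fell and grey points did not pass; medians run from -2.53 for skeletal muscle genes to 1.51 for cell cycle genes.

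Across the 42 lists, camera with its preset correlation called 14 up and 7 down, and 0 of these calls held with an estimated correlation. That alternative recovered 0 of 3 shifted lists in simulation, and its smallest adjusted p over the 42 lists was 0.55. It therefore cannot tell shifted lists from others. Fry, which asks whether the genes of a list move one way on balance, called 2 lists, adipocyte and Schwann cell and nerve genes, both down (adjusted p = 0.0479 for each). Its mixed test, for changes in either direction, called 41.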

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

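Both results below come from a test named before the data were examined, that of all probe sets. Among the 16010 probe sets with no gene symbol, which enter no comparison of genes, 101 were higher and 216 lower in arthritic synovium. Among the 1814 probe sets with several symbols 24 were higher and 15 lower. They are given here because these data carry no single gene name. Among the 23521 probe sets with 1 symbol a larger share passed, 560 higher and 550 lower. Probe set 17306983 rose by at least 4.12 ± 0.56 (SE) on the log2 scale, from nonarthritic values of 4.91 and 4.50 not shown to be above background. It read 9.67 and 7.99 in arthritic pools 1 and 2, so its fold change is less certain. Probe set 17218752 was at -4.90 ± 0.21.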

How the results depend on the processing

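Every alternative here was planned before the data were examined. The main counts were 1933 genes higher and 1469 lower. Testing all 41345 probe sets gave 685 and 781, with a prior of 3.22 degrees of freedom in place of 5.98, and a 2-fold limit gave 766 and 689. The other full-data settings gave 1216 to 2749 higher and 1027 to 2079 lower. All 3402 called genes kept their sign in each setting that tested them, which for most settings was fixed in advance. Other priors and thresholds, the dim-gene filter, the block and the test of all probe sets leave the fold changes unchanged. With 1 pool left out, groups that do not overlap cannot change sign. Leaving out 1 pool gave 47 to 637 higher and 105 to 584 lower, with fewer samples and 1 residual degree of freedom. The pool numbers do not pair the samples, which are different mice; pool 1 minus pool 2 differences of the groups correlated at r = 0.18 across genes. With pool number as a replicate block, 1216 genes were higher and 1027 lower, and Wnt antagonists were no longer called (adjusted p = 0.0523). Of the lists, 14 shifted up and 7 down; 9 shifted up with the dim-gene filter and 9 with quantile normalization again, 0 up and 0 down with an estimated correlation, and 0 up and 2 down with fry. Leaving out pools gave 13 to 14 lists up and 5 to 8 down. Some uncalled results changed direction. In some lists only the direction given by camera or fry changed, while the median kept its sign. These were MHC class II genes (median -0.0375, and -0.0116 with quantile normalization again) and, with fry, synovial fibroblast (-0.02) and chondrocyte genes (0.60). Medians of synovial fibroblast genes ran from -0.065 to 0.0525 over the pools left out, above 0 without nonarthritic pool 1. Gapdh was at -0.035 without nonarthritic pool 1 and 0.145 without nonarthritic pool 2. Immediate early genes had medians of 0.065 without nonarthritic pool 1, 0.19 without arthritic pool 1 and -0.27 without arthritic pool 2. The cause was not tested except where given. Without detection calls, signal over background is unknown.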

Other observations

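The macrophage and histone lists of this paragraph were put together after the gene values were seen, so their tests do not give independent evidence. Genes of resident macrophages and of macrophages exposed to interleukin-4 fell in 11 of 20 measured cases and rose in 2, Ccl8 (1.55) and Igfbp4 (1.05), with a median log2 fold change of -1.01. Besides Retnla, Ccl17 and Lyve1, the lectins Mgl2 (-2.82) and Cd209d (-2.71) and the folate receptor Folr2 (-1.27) fell, while the mannose receptor Mrc1 was at -0.27. Genes of inflammatory monocytes and macrophages rose in 14 of 20 cases and fell in 0 (median 1.83), among them Acod1 (3.62), Clec4e (3.33), Clec4n (2.79) and Slfn4 (3.04). Of these 20 genes, 17 are also in lists fixed earlier, and several are made by neutrophils too. Camera gave adjusted p = 1.19e-06 and 1.03e-10 over the 3 added lists, and adjusted p = 0.101 for both with an estimated correlation. Histone genes of the replication-dependent clusters rose in 12 of 26 cases and fell in 1 (median 0.68, camera adjusted p = 8.71e-07; adjusted p = 0.139 with an estimated correlation). H1f5 (3.84), H2bc12 (2.78) and H2ac15 (2.76) led them; such genes have near-identical copies and are transcribed while DNA replicates.

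In the patterns below, all tests but that of genomic DNA were written after the results they measure had been seen. The muscle, adipocyte and nerve lists fell while many others rose. After quantile normalization again, the median of their 61 members stayed at -2.06 (95% resampling interval -2.38 to -1.47). The deposited values were already normalized, and no gene's log2 fold change moved by more than 0.18. The test therefore cannot decide whether normalization between arrays contributed. A smaller share of muscle, fat and nerve tissue, by dissection or by dilution with infiltrating cells, cannot be told apart from lower expression within muscle and fat cells. That 59 of all 61 members (96.7%) were lower restates the pattern and goes with both; a first count, over the 54 members above the median level of all genes, was limited to these after the values were seen. The muscle fold changes spread with an SD of 1.26, which decides nothing either, since bulk values hold no cell counts.

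If only muscle, fat and nerve tissue were lost, all remaining cell types would rise alike. Blood vessel genes were taken as the measure of that rise. Vessels within the lost tissue would go with it, so this measure may be too low. The cell cycle median lay 1.17 above that of blood vessel genes (0.83 to 1.68, resampling genes and not pools). Cell cycle genes thus rose more than blood vessel genes. Their median was 1.51, while synovial fibroblast genes had a median of -0.02, with 4 of 20 rising and 5 falling. Macrophage and monocyte genes had a median of 0.22, with 9 of 26 rising and 4 falling. These lists too may read low if the lost tissue held such cells. The values argue against such loss as the whole cause of the cell cycle rise, but not against a part in it. The ribosomal protein median lay 0.13 above that of blood vessel genes (-0.13 to 0.58). For ribosomal protein genes, loss of tissue cannot be told apart from a change of their own. The bounds for the muscle spread and for ribosomal genes were reworded after these values were known, which changed no outcome. Arthritis itself, the group difference of the design, stays open as an untested biological explanation.

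Nonarthritic pool 1 lay above nonarthritic pool 2 in 25 of the 27 genes that rose at least 8-fold. For compressed values on the pool 2 array, the median difference was 0.73 relative to genes of the same level (0.57 to 1). That level was the mean over all arrays, and it includes the arthritic arrays, where these genes read at least 8-fold higher. The genes they were compared with could therefore be brighter on the nonarthritic arrays. The test thus cannot decide whether compression contributed. Over all probe sets, values had an SD of 2.13 on nonarthritic pool 1 and 2.07 on nonarthritic pool 2. Their quartiles were 5.73 and 8.75 on pool 1, and 5.87 and 8.68 on pool 2. Any compression of the whole array was thus slight beside a median difference of 0.73. Carry-over of arthritic RNA at 1 fixed share was tested next. The share needed ran from 1.15% at the 10th percentile of the genes to 11.9% at the 90th. It was 17.5% for Mmp13 and 0 for Mmp8. The test allowed for no spread between the nonarthritic pools, whose gene differences had an SD of 0.32. Such spread also widens the shares, so carry-over stays undecided. No biological explanation was tested, since the labels give no difference between these pools.

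Olfactory and vomeronasal receptor genes read highest on nonarthritic pool 2 in 1027 of 1390 cases (73.9%), where chance gives 25% and all genes gave 28.3%. Of the 224 genes at least 2-fold higher on pool 2 than on pool 1, 111 were such receptors, and 31 genes were 2-fold higher on pool 1. Compression by signal level alone is argued against, since the receptors lay at -0.23 (-0.26 to -0.20) relative to other genes of the same level. Genomic DNA in that RNA may contribute, as a hypothesis: dim probe sets with several symbols, 677 in number, lay at -0.18 (-0.27 to -0.12) relative to those with 1 symbol, in the direction it predicts. No biological explanation was tested, and 33 of the 1469 genes that fell are such receptors.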
